A study of Homo sapiens with 12 samples.

How the data were processed

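The deposited table holds a probe set intensity for each of 12 single-colour Affymetrix arrays, made by the authors with RMA in Transcriptome Analysis Console according to the submitters' processing notes, and the values are linear intensities. How the arrays were scaled against each other is not stated. ERCC spike-in RNA was added before extraction, but whether it was used for scaling is not stated either. The genome build and the array annotation are not given in the sources used here. The log2 of every deposited value was taken. Versions of the submitters' tools are not given.

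The table has 29592 rows. A probe table linked 14783 of them to 1 gene symbol and 0 to several, and 14809 had no gene name here. Symbols were brought up to date with the RefSeq gene table of GRCh38.p14, which served for names only. This gave 14599 genes (11734 protein-coding, 1361 long non-coding RNA, 1020 microRNA). Where a gene had more than 1 row, as 169 did, the row with the highest mean was used. No spike-in rows could be identified.

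Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 12 arrays with a mean per group, which leaves 8 residual degrees of freedom and 7.68 prior degrees of freedom. Every adjusted p for a gene is a moderated limma p adjusted by Benjamini-Hochberg over 14599 genes, and a gene passed at an adjusted p under 0.05. There were 6 comparisons: each treatment against vehicle, the combination against MAPKi and against HDACi, and the interaction, which is (combination minus MAPKi) minus (HDACi minus vehicle). Having 3 arrays per group limits the precision of every estimate, and standard errors are limma's.

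Before the data were examined, 32 gene lists were fixed, of whose 523 memberships 308 were measured. Their shifts were tested with camera in limma against all other genes, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Genes were counted as higher or lower after adjustment over all genes and over the list alone. The comparisons, their tests and thresholds, and the alternatives listed below were also chosen before the data were examined, whereas some tests of explanations in the closing part were chosen afterwards and are named there. Genes to name were set by a rule of the same date: the 10 largest rises and 10 largest falls per comparison among passing genes whose arrays did not overlap between groups, up to 4 passing and 2 non-passing genes per list, and a set of fixed genes, 14 of which had a named row. All genes named were drawn from that rule.

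All comparisons were repeated after quantile normalization of the deposited log2 values, after subtraction of each array's median, without the dimmest 40% of genes, with trend and robust variance in eBayes, with the mean of a gene's probe sets, with all probe sets, with only the arrays compared, with the replicate number as a block, and without each array in turn. Scaling on spike-in rows was planned and not run, since none could be identified. Titles number the arrays of each group 1 to 3. After group means were removed, r across genes between arrays of the same number had a median of 0.0324, against -0.0111 for other pairs. The lowest same-number r was -0.106, but 9 of 12 arrays correlated best with their own number. Between HDACi and combination arrays, same-number r was 0.108, 0.121 and 0.085, and other pairs had -0.074 to -0.031. Genes are not independent replicates. A batch shared by number is thus not excluded. The main fit did not treat the arrays as paired, and the block fit allows for it.

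The fit was tested on simulated data with the vehicle means and limma spreads of the 14599 genes, compared as MAPKi against vehicle. It called 58% of genes changed by 0.5 on the log2 scale, 98% of those changed by 1 and 100% of those changed by 2 or 4, along with 8 unchanged genes. A list shifted by 0.5 was called with both correlations, and 0 unshifted lists were called with the preset correlation. Simulated noise was independent between genes, few genes were changed and no general shift was added. The simulation therefore cannot show how camera or the gene calls behave with correlated genes or under a general shift. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Rows with no gene name were counted but not analysed further here.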

Results

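Gene expression was measured on 12 arrays in Hs695T, a human melanoma cell line, 24 h after drug treatment. Of these, 3 arrays each came from cells given vehicle (DMSO), MAPKi, HDACi, or MAPKi and HDACi together (the combination). MAPKi was 100 nM of the BRAF inhibitor dabrafenib with 10 nM of the MEK inhibitor trametinib. HDACi was 1 µM of entinostat, an inhibitor of class I histone deacetylases. Sample titles call the arrays of a group biological replicates, whereas the series description calls them technical triplicates, so every p-value below covers only the spread between these arrays. Named probe sets covered 14599 genes, and the number of arrays limits the precision of each value. Pearson's r across probe sets was 0.989 to 0.994 between arrays of the same group, which describes similarity and not precision, since probe sets are not independent replicates.

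Signal was lower over most of the array after MAPKi, alone or in the combination. Median intensity per array was 53.3 ± 3.77 in vehicle (mean ± SD, n = 3), 39.3 ± 1.68 with MAPKi and 36.0 ± 3.46 with the combination, and all 6 MAPKi-treated arrays lay below all 3 vehicle arrays. With HDACi it was 49.7 ± 1.68, overlapping vehicle in 1 of 3 arrays (51.56, lowest vehicle array 50.64), while mean intensity did not overlap (154.8 ± 4.55 against 191.2 ± 12.1). The median log2 change over all genes was -0.48 for MAPKi, -0.20 for HDACi and -0.72 for the combination against vehicle. Dim genes moved little and bright genes most. With genes placed in 10 equal bins by mean intensity, the median change with the combination went from -0.04 in the dimmest bin to -1.19 in the brightest. Changes below are log2 differences of the deposited intensities ± the limma standard error (3 arrays per group), and "quantile" marks the change after quantile normalization of the same values, which leaves median changes of 0.01, -0.04 and -0.03. A gene is said to have risen or fallen where it passed on the deposited scale.

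**Figure D1:**
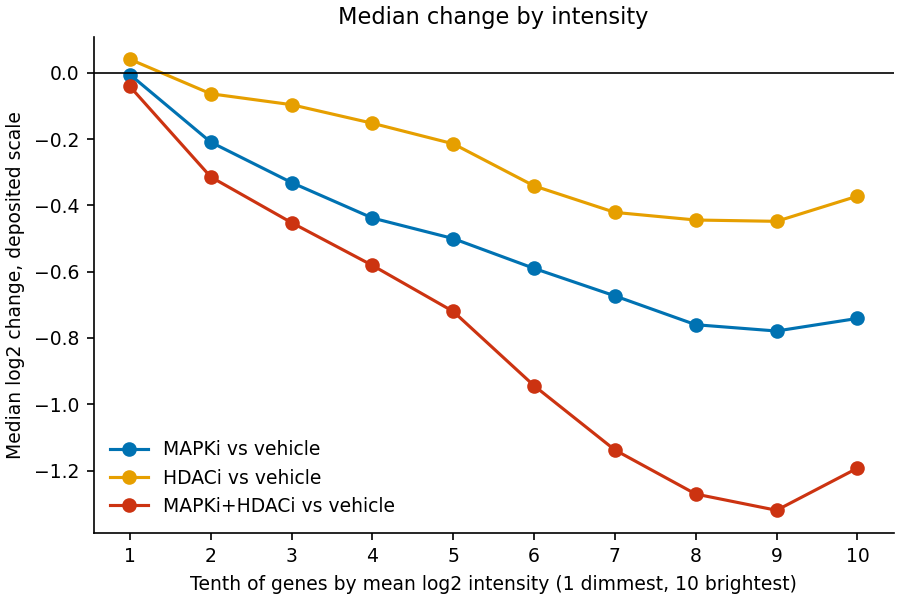
Median log2 change of genes (y axis, deposited scale) in 10 equal bins of genes by mean log2 intensity (x axis, 1 dimmest to 10 brightest), against vehicle, with a line per treatment. The combination reaches -1.32 in bin 9, MAPKi -0.78 and HDACi -0.45.

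MAPK inhibition alone was compared with vehicle to see what the BRAF and MEK inhibitors changed within a day. The 10 largest falls included feedback inhibitors of the MAPK pathway and ETS transcription factors. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, went from a log2 intensity of 11.17 ± 0.12 to 5.09 ± 0.08 (SD, n = 3), 67.6-fold lower (adjusted p = 1.2e-14, quantile -5.45). SPRY2 fell 29.1-fold (-4.87 ± 0.12, quantile -4.11) and the ERK phosphatase DUSP6 fell 23.0-fold (-4.52 ± 0.17, quantile -3.78). The ETS transcription factors ETV5 (-4.73 ± 0.14, quantile -3.98), ETV4 (-4.69 ± 0.12, quantile -3.93) and ETV1 (-4.13 ± 0.15, quantile -3.37) fell together. NPPC, which encodes C-type natriuretic peptide, fell 39.1-fold (-5.29 ± 0.11, quantile -4.71).

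All 16 measured genes of the MAPK pathway output list fell on both scales, with a median of -2.85 (quantile -2.11). Its camera adjusted p was 1.2e-11, with adjusted p = 0.28 with an estimated correlation (0.0021 after quantile normalization). CCND1, which encodes cyclin D1, fell by 2.69 ± 0.11 (quantile -1.93), and MYC fell by 1.63 ± 0.13 (quantile -0.91). Other genes among the 10 largest falls were TRIB1 (-4.04 ± 0.11, quantile -3.25), CEMIP (-4.03 ± 0.11, quantile -3.44) and EFNA5, an ephrin (-3.90 ± 0.12, quantile -3.10). Of 13 immediate early and AP-1 genes, 8 fell and 1 rose, and after quantile normalization 6 fell and 5 rose, with a median of -0.76 (quantile 0.06, so of opposite sign, camera adjusted p = 0.79). Its strongest fall was FOSL1, an AP-1 subunit (-3.72 ± 0.15, quantile -2.94), while JUN did not pass (0.12 ± 0.10) but did after quantile normalization (0.93).

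Cell cycle genes were lower after MAPKi. All 20 measured DNA replication genes fell, with a median of -2.33 (quantile -1.57, 17 lower and 1 higher), camera adjusted p = 2.2e-10 and adjusted p = 0.41 with an estimated correlation (0.0078 after quantile normalization). They included the replication licensing and firing factors MCM10 (-3.50 ± 0.11, quantile -2.70), MCM5 (-3.00 ± 0.12, quantile -2.25) and CDC6 (-2.90 ± 0.12, quantile -2.11). All 20 mitosis genes fell as well, with a median of -1.54 (quantile -0.79, 19 lower), camera adjusted p = 8.9e-09 and adjusted p = 0.41 with an estimated correlation (0.041 after quantile normalization). CDK1 (-2.06 ± 0.13, quantile -1.27) and AURKB (-2.06 ± 0.13, quantile -1.25), kinases that drive mitosis, fell alike. MKI67, a proliferation marker, fell by 1.59 ± 0.10 (quantile -0.86). The 3 measured cell cycle brakes all fell (median -0.67, quantile 0.14, so of opposite sign, camera adjusted p = 0.63).

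Growth and metabolic genes were also lower. All 10 ribosome biogenesis genes fell on both scales (median -1.36, quantile -0.61), camera adjusted p = 0.00012 and adjusted p = 0.41 with an estimated correlation (0.01 after quantile normalization), among them NOLC1 (-1.55 ± 0.11, quantile -0.75). All 12 sterol synthesis genes fell (median -0.90, quantile -0.23 with 6 lower), camera adjusted p = 0.00085 and adjusted p = 0.41 with an estimated correlation. All 7 glycolysis genes fell (median -1.16, quantile -0.39 with 5 lower), including HK1 (-1.61 ± 0.11, quantile -0.82), camera adjusted p = 0.018 and adjusted p = 0.41 with an estimated correlation. All 9 mitochondrial respiration genes fell (median -0.85), camera adjusted p = 0.029 and adjusted p = 0.41 with an estimated correlation, but 0 passed after quantile normalization (median -0.11). Housekeeping genes fell too, with list medians of -1.067, -1.046 and -1.136 in the 3 MAPKi arrays (quantile -0.325, -0.29 and -0.226). Camera does not match genes on intensity, and the brightest bin had a median change of -0.74. On the deposited scale the falls in sterol synthesis, glycolysis and respiration genes were therefore not told apart from the general shift.

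Receptor genes mostly fell. Of 10 receptor tyrosine kinases 9 fell (median -1.50, quantile -0.81 with 7 lower and 2 higher), camera adjusted p = 0.0061 and adjusted p = 0.41 with an estimated correlation. EGFR (-2.31 ± 0.11, quantile -1.54) and MET (-1.84 ± 0.10, quantile -1.23) were among them. Of 12 genes of the dedifferentiated and invasive melanoma state, 10 fell and 1 rose (median -1.13, quantile -0.44 with 8 lower and 2 higher, camera adjusted p = 0.097), including NGFR (-1.98 ± 0.10, quantile -1.17).

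Against this fall, few genes rose after MAPKi. ANGPTL7, which encodes a secreted angiopoietin-like protein, went from 5.28 ± 0.24 to 10.78 ± 0.17 (SD, n = 3), 45.1-fold higher (adjusted p = 5.4e-14, quantile 5.90). GPNMB, a melanosomal glycoprotein, rose 9.98-fold (3.32 ± 0.14, quantile 3.72). The adaptor gene FYB1 (3.13 ± 0.15, quantile 3.34), the matrix gene MATN2 (2.61 ± 0.12, quantile 3.09) and the adhesion gene ALCAM (2.45 ± 0.11, quantile 2.93) rose too, as did PI15 (2.71 ± 0.17, quantile 2.97), LCTL (2.38 ± 0.09, quantile 3.00), TMEM47 (2.28 ± 0.12, quantile 2.86) and STK32A (2.25 ± 0.12, quantile 2.60). The pro-apoptotic BH3-only genes BMF (1.77 ± 0.11, quantile 2.37) and BCL2L11 (0.93 ± 0.11, quantile 1.65) rose, while the survival genes BCL2 (-2.45 ± 0.15, quantile -1.80) and MCL1 (-1.60 ± 0.11, quantile -0.83) fell. Of 13 apoptosis regulators 2 rose and 9 fell (median -0.55, quantile 0.04 with 3 each way), and camera, which compares with other genes, placed the list above them without passing (adjusted p = 0.73). Among 13 melanocyte differentiation genes 1 rose and 6 fell (median -0.23, quantile 0.04 with 4 higher and 1 lower), and camera did not pass (adjusted p = 0.056, direction above other genes). MITF, the melanocyte master regulator, did not pass (0.12 ± 0.13, adjusted p = 0.42) but did after quantile normalization (0.61). MLANA did not pass on either scale (-0.04 ± 0.11, adjusted p = 0.74, quantile 0.19), and PMEL, a melanosome matrix gene, fell by 0.60 ± 0.14 without passing after quantile normalization (quantile -0.11).

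Homologous recombination genes were mostly lower after MAPKi. Of 17 homologous recombination genes 16 fell (median -1.37, quantile -0.56 with 12 lower and 2 higher), camera adjusted p = 1e-05 and adjusted p = 0.41 with an estimated correlation (0.017 after quantile normalization). EXO1 (-3.06 ± 0.11, quantile -2.27) and BRIP1 (-2.61 ± 0.11, quantile -1.83) fell most. Base excision repair fell in 14 of 15 (median -0.97, quantile -0.27 with 7 lower and 1 higher), camera adjusted p = 0.0061 and adjusted p = 0.42 with an estimated correlation, and mismatch repair in 6 of 6 (median -0.84, quantile -0.16 with 2 lower and 1 higher), camera adjusted p = 0.037 and adjusted p = 0.41 with an estimated correlation. Housekeeping list medians were -1.046 to -1.136 in the MAPKi arrays. On the deposited scale the falls in base excision and mismatch repair genes were therefore not told apart from the general shift. Camera did not pass for non-homologous end joining (6 of 6 lower, median -0.96, quantile -0.22 with 2 lower, adjusted p = 0.066), Fanconi anaemia (3 of 3 lower on both scales, median -1.17, quantile -0.36, adjusted p = 0.06), direct reversal and translesion synthesis (3 of 5 lower, median -0.39, quantile 0.11 with 2 each way, adjusted p = 0.76) or the 1 nucleotide excision repair gene (-0.99, quantile -0.22, adjusted p = 0.46). The Ku subunits XRCC5 (-0.95 ± 0.10, quantile -0.28) and XRCC6 (-1.03 ± 0.11, quantile -0.22) fell, the latter without passing after quantile normalization. PARP1 fell by 1.10 ± 0.10 (quantile -0.33), and MGMT fell by 0.39 ± 0.11 but was 0.11 higher, without passing, after quantile normalization. In total 10094 genes changed after MAPKi, 434 higher and 9660 lower, against 2205 higher and 2028 lower after quantile normalization. On both scales 371 genes were higher and 2023 lower, and 852 genes that fell on the deposited scale were called higher after quantile normalization. Adjusted over the list alone, the deposited-scale list counts given here and below were the same except where another count stands beside them, and no list passed with an estimated correlation on that scale.

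**Figure D2:**
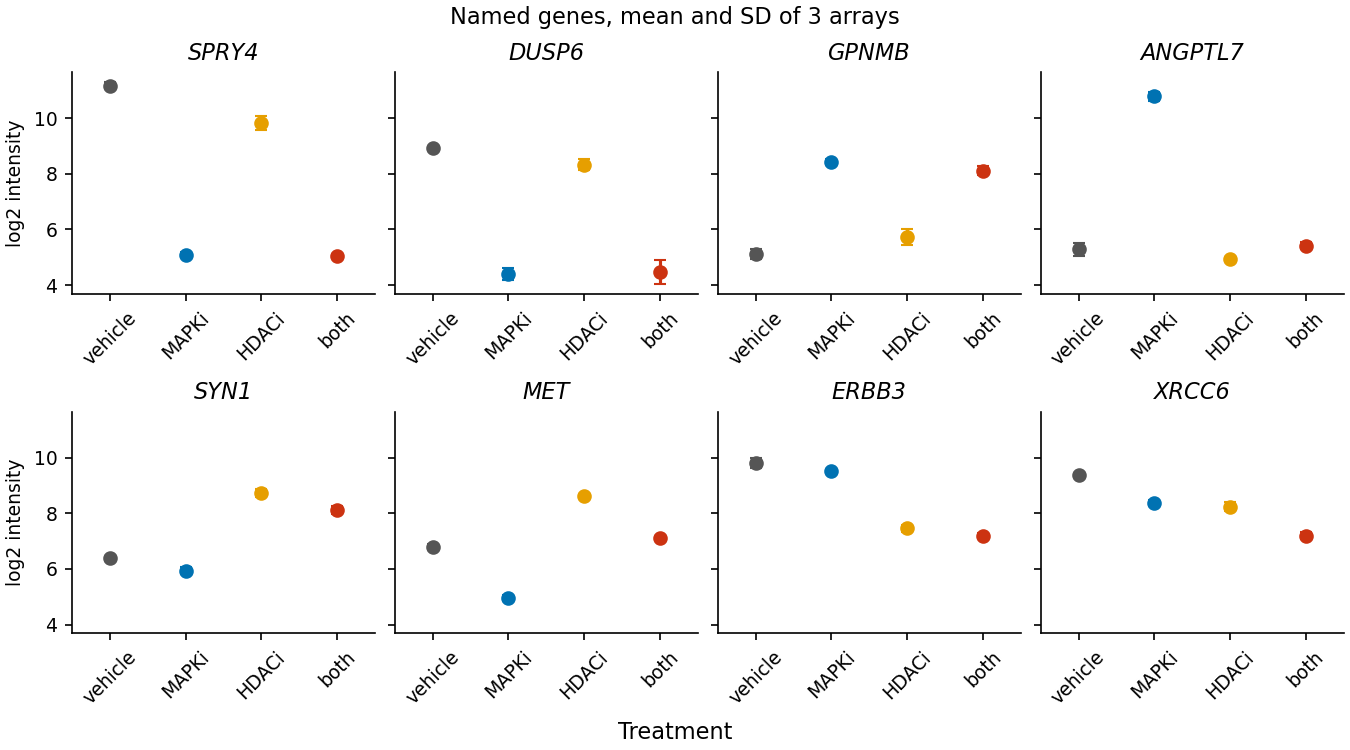
Mean log2 intensity (y axis) of 8 genes in vehicle, MAPKi, HDACi and both (x axis), with bars for the SD of 3 arrays. SPRY4 falls from 11.17 to 5.09 with MAPKi, and ANGPTL7 reaches 10.78 with MAPKi alone and 5.41 with both.

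HDAC inhibition alone was compared with vehicle to see what entinostat changed. TREM1, a receptor of myeloid cells, went from 5.23 ± 0.11 to 8.71 ± 0.04 (SD, n = 3), 11.1-fold higher (adjusted p = 5.1e-10, quantile 3.48). ENPP5 rose 10.1-fold (3.34 ± 0.11, quantile 3.29), and EFNB2, which encodes ephrin-B2, rose 9.99-fold (3.32 ± 0.14, quantile 3.28). Further rises were VAT1L (3.14 ± 0.12, quantile 3.44), the collagenase gene MMP13 (3.10 ± 0.21, quantile 2.97), CALB2, which encodes calretinin (3.03 ± 0.10, quantile 3.17), and the NAD synthesis gene NMNAT2 (2.84 ± 0.13, quantile 3.12). The deubiquitinase gene USP17L15 (3.28 ± 0.21, quantile 3.14) and its relative USP17L12 (2.87 ± 0.19, quantile 3.01) rose, and USP17L9P had values identical to USP17L12 from its brighter probe set and 0.57 from the other.

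Of 14 measured neuronal genes 8 rose and 1 fell after HDACi (2 fell adjusted over the list alone), with a median of 0.52 (quantile 0.66, 9 higher and 0 lower), camera adjusted p = 4.9e-05 and adjusted p = 0.61 with an estimated correlation. The synaptic vesicle genes SYN1 (2.33 ± 0.12, quantile 2.50), SYT4 (1.49 ± 0.22, quantile 1.44) and SYT11 (1.42 ± 0.11, quantile 1.82) were among them. Of 7 inflammatory secretion genes 4 rose and 0 fell (median 0.40, quantile 0.79 with 5 higher), camera adjusted p = 0.00089 and adjusted p = 0.61 with an estimated correlation. They were the chemokine genes CXCL8 (2.24 ± 0.16, quantile 2.12) and CCL2 (0.40 ± 0.10, quantile 0.79), the collagenase gene MMP1 (1.31 ± 0.11, quantile 1.29) and the adhesion gene ICAM1 (1.25 ± 0.12, quantile 1.70). The receptor gene MET rose by 1.86 ± 0.10 (quantile 2.08). The BH3-only genes PMAIP1 (1.26 ± 0.10, quantile 1.59), BCL2L11 (0.99 ± 0.11, quantile 1.30) and BIK (0.98 ± 0.21, quantile 1.03) rose, within an apoptosis list of 13 with 3 higher and 6 lower (median -0.23, quantile 0.10, so of opposite sign, camera adjusted p = 0.79). Of 7 p53 targets, GDF15 alone rose (1.41 ± 0.12, quantile 1.65) and 3 fell, including BAX (-1.10 ± 0.11, quantile -0.67), with a camera adjusted p of 0.9.

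The melanocyte genes split. EDNRB (1.07 ± 0.12, quantile 1.19) and PMEL (1.07 ± 0.14, quantile 1.22) rose, whereas SOX10, a neural crest transcription factor, fell by 1.09 ± 0.12 (quantile -0.74), with 3 of 13 higher and 3 lower (median -0.04, mean 0.04, quantile median -0.06 with 5 higher and 2 lower, camera adjusted p = 0.16). MITF did not pass (-0.30 ± 0.13, adjusted p = 0.06, quantile -0.15), and MLANA fell by 0.36 ± 0.11 without passing after quantile normalization (quantile -0.31). The largest falls after HDACi were FST, which encodes the activin-binding protein follistatin (-2.73 ± 0.14, quantile -2.31), the Polycomb-associated gene PHF19 (-2.64 ± 0.12, quantile -2.20), FXYD3, a regulator of the sodium pump (-2.59 ± 0.12, quantile -2.16), and the kinase gene WNK4 (-2.43 ± 0.14, quantile -1.98). ERBB3, a receptor for neuregulins, fell 5.06-fold (-2.34 ± 0.11, quantile -1.95), and of the 10 receptor tyrosine kinases 2 rose and 5 fell (camera adjusted p = 0.87). Among the 11 histone deacetylase genes 1 rose and 5 fell (median -0.28, quantile 0.03 with 4 higher and 2 lower, camera adjusted p = 1), with HDAC9 higher (0.75 ± 0.13, quantile 0.85) and HDAC7 lower (-0.77 ± 0.13, quantile -0.38). Of 12 interferon response genes 4 rose and 3 fell (4 fell adjusted over the list alone), with IFIT1 higher (1.02 ± 0.16, quantile 0.99) and IFIT3 lower (-0.77 ± 0.16, quantile -0.67), at a median of 0.02 and a mean of -0.01 (camera adjusted p = 0.22).

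DNA replication genes and 3 of the repair lists were lower after HDACi. Of 20 DNA replication genes 17 fell and 0 rose (median -1.24, quantile -0.80 with 13 lower), camera adjusted p = 3.9e-06 and adjusted p = 0.67 with an estimated correlation, led by MCM5 (-2.29 ± 0.12, quantile -1.93) and MCM2 (-1.72 ± 0.12, quantile -1.28). Mitosis genes did not follow: of 20, 8 fell and 1 rose (median -0.22, quantile 0.13 with 8 higher and 3 lower, so of opposite sign, camera adjusted p = 0.87), and MKI67 did not pass (-0.22 ± 0.10, adjusted p = 0.085, quantile 0.11). All 6 non-homologous end joining genes fell on both scales (median -0.82, quantile -0.49), camera adjusted p = 0.0049 and adjusted p = 0.61 with an estimated correlation. They included TP53BP1 (-1.35 ± 0.13, quantile -0.97), XRCC6 (-1.15 ± 0.11, quantile -0.77) and XRCC5 (-0.82 ± 0.10, quantile -0.57). Of 15 base excision repair genes 13 fell (median -0.64, quantile -0.28 with 11 lower and 1 higher), camera adjusted p = 0.0011 and adjusted p = 0.67 with an estimated correlation, with UNG, the uracil-DNA glycosylase, lowest (-2.18 ± 0.11, quantile -1.73) and PARP1 at -0.64 ± 0.10 (quantile -0.29). Of 17 homologous recombination genes 15 fell (median -0.60, quantile -0.23 with 9 lower), camera adjusted p = 0.0011 and adjusted p = 0.67 with an estimated correlation. The other repair lists did not pass camera: of 6 mismatch repair genes 4 fell and 1 rose (median -0.32, quantile 0.06 with 1 each way, so of opposite sign, camera adjusted p = 0.56), of 3 Fanconi anaemia genes 2 fell (median -0.31, quantile -0.04 with 1 each way, camera adjusted p = 0.68), of 5 direct reversal and translesion synthesis genes 4 fell (median -0.53, quantile -0.21 with 2 lower, camera adjusted p = 0.16), and the 1 nucleotide excision repair gene fell (-0.57, quantile -0.21, camera adjusted p = 0.48). MGMT, which reverses alkylation damage, fell by 0.70 ± 0.11 (quantile -0.54).

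MAPK pathway output genes went both ways after HDACi. Of 16, 10 fell and 2 rose (median -0.56, quantile -0.16 with 6 lower and 5 higher, camera adjusted p = 0.25), with SPRY4 at -1.33 ± 0.12 (quantile -1.07) and DUSP5, another dual-specificity phosphatase, at 1.29 ± 0.15 (quantile 1.42). DUSP6 (-0.60 ± 0.17, quantile -0.19) and ETV5 (-0.61 ± 0.14, quantile -0.21) fell without passing after quantile normalization. CCND1 did not pass (-0.20 ± 0.11, adjusted p = 0.14, quantile 0.16), nor did MYC (-0.09 ± 0.13, adjusted p = 0.61), which was called higher by 0.28 after quantile normalization. In total 6937 genes changed after HDACi, 1513 higher and 5424 lower, against 2696 higher and 3082 lower after quantile normalization, with 1445 higher and 3058 lower on both.

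The combination was compared with vehicle for the joint effect of the 3 drugs. SPRY4 was 68.8-fold lower (-6.10 ± 0.12, adjusted p = 1.4e-14, quantile -5.36), FOSL1 24.9-fold lower (-4.64 ± 0.15, quantile -3.76) and the replication gene MCM5 15.2-fold lower (-3.92 ± 0.12, quantile -2.80). FYB1 was 9.08-fold higher (3.18 ± 0.15, quantile 3.84) and GPNMB 8.00-fold higher (3.00 ± 0.14, quantile 3.86). Other large rises were SLPI, a protease inhibitor (2.88 ± 0.19, quantile 3.77), EFNB2 (2.68 ± 0.14, quantile 3.53), the chemokine gene CXCL14 (2.50 ± 0.14, quantile 3.39), CD24 (2.47 ± 0.12, quantile 3.53) and CALB2 (2.37 ± 0.10, quantile 3.36). All 16 MAPK pathway output genes fell (median -3.01, quantile -1.97 with 14 lower and 1 higher), camera adjusted p = 1.7e-05 and adjusted p = 0.55 with an estimated correlation (0.025 after quantile normalization). ETV5 (-4.69 ± 0.14, quantile -3.84), DUSP6 (-4.45 ± 0.17, quantile -3.62), CCND1 (-2.58 ± 0.11, quantile -1.33) and MYC (-1.44 ± 0.13, quantile -0.37) were lower. GNE, an enzyme of sialic acid synthesis, fell by 3.81 ± 0.11 (quantile -2.63).

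Every measured gene of the DNA repair lists fell with the combination on the deposited scale, but fewer did after quantile normalization. Homologous recombination fell in 17 of 17 (median -1.82, quantile -0.89 with 13 lower and 2 higher), camera adjusted p = 0.00035 and adjusted p = 0.55 with an estimated correlation (0.041 after quantile normalization). EXO1 (-2.72 ± 0.11, quantile -1.59) and XRCC2 (-2.71 ± 0.12, quantile -1.46) led. Non-homologous end joining fell in 6 of 6 on both scales (median -2.00, quantile -0.89), camera adjusted p = 0.02 and adjusted p = 0.55 with an estimated correlation. XRCC6 was 4.61-fold lower (-2.20 ± 0.11, quantile -0.92), RIF1 fell by 2.29 ± 0.11 (quantile -1.02) and XRCC5 by 1.71 ± 0.10 (quantile -0.69). Base excision repair fell in 15 of 15 (median -1.58, quantile -0.43 with 9 lower and 1 higher), camera adjusted p = 0.0033 and adjusted p = 0.55 with an estimated correlation (0.031 after quantile normalization), with UNG 13.1-fold lower (-3.71 ± 0.11, quantile -2.74), APEX1 at -2.35 ± 0.12 (quantile -1.10) and PARP1 at -1.68 ± 0.10 (quantile -0.43).

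The smaller repair lists did not pass camera. The Fanconi anaemia list fell in 3 of 3 (median -1.42, quantile -0.20 with 2 lower, camera adjusted p = 0.22) and mismatch repair in 6 of 6 (median -1.29, quantile -0.13 with 2 lower and 1 higher, camera adjusted p = 0.074), including PMS2 (-2.35 ± 0.11, quantile -1.07). Direct reversal and translesion synthesis fell in 5 of 5 (median -1.06, quantile -0.02 with 2 lower and 1 higher, camera adjusted p = 0.13), including the ubiquitin ligase gene RAD18 (-3.16 ± 0.11, quantile -1.97) and MGMT (-1.23 ± 0.11, quantile -0.64). The nucleotide excision repair list had 1 measured gene, RAD23B, which fell by 1.53 ± 0.10 (quantile -0.34, camera adjusted p = 0.38).

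Growth genes fell with the combination as well. All 20 DNA replication genes fell (median -2.40, quantile -1.22 with 16 lower and 2 higher), camera adjusted p = 1.2e-05 and adjusted p = 0.55 with an estimated correlation (0.031 after quantile normalization). All 10 ribosome biogenesis genes fell (median -2.08, quantile -0.83 with 9 lower), camera adjusted p = 0.00073 and adjusted p = 0.55 with an estimated correlation (0.025 after quantile normalization). Mitosis genes turned with the scale: 19 of 20 fell on the deposited scale (median -0.89, camera adjusted p = 0.18), and 11 were higher and 2 lower after quantile normalization (median 0.29). MKI67 fell by 1.07 ± 0.10 but stood at 0.01 after quantile normalization. Neuronal genes turned too, with 3 of 14 higher and 7 lower (median -0.21) against 9 higher and 1 lower (quantile median 0.67). Camera placed that list above other genes on both scales (adjusted p = 0.00035, and adjusted p = 0.55 with an estimated correlation). SYT4 (1.94 ± 0.22, quantile 2.63) and SYN1 (1.73 ± 0.12, quantile 2.77) rose on both scales. The same turn was seen for 3 antigen presentation genes (0 higher and 3 lower, then 3 higher, medians -0.82 and 0.39), 10 lysosome genes (0 higher and 10 lower, then 6 higher and 1 lower, medians -0.83 and 0.28) and 11 amino acid and stress response genes (0 higher and 9 lower, then 7 higher and 1 lower, medians -0.59 and 0.59), with camera adjusted p of 0.51, 0.34 and 0.96 on the deposited scale. BCL2L11 rose by 1.01 ± 0.11 (quantile 2.20) and MITF fell by 0.97 ± 0.13 (quantile -0.34), without passing once each array's median was subtracted (-0.17, adjusted p = 0.13). PMEL did not pass (-0.26 ± 0.14, adjusted p = 0.1) and was called 0.54 higher after quantile normalization, and MLANA fell by 0.51 ± 0.11 without passing after quantile normalization (quantile -0.24).

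In total 11479 genes changed with the combination, 639 higher and 10840 lower, against 3225 higher and 3530 lower after quantile normalization. On both scales 584 were higher and 3525 lower, and 1718 that fell on the deposited scale were called higher after quantile normalization. Of 5 housekeeping genes 5 fell (median -1.33, quantile -0.05, camera adjusted p = 0.13), so no control gene held its level on the deposited scale. Markers of other cell types did not rise on the deposited scale: 6 of 9 keratinocyte and epithelial markers (camera adjusted p = 0.34), 2 of 4 fibroblast and endothelial markers (0.34) and 3 of 4 leukocyte markers (0.85) fell. After quantile normalization 3, 0 and 1 of them, in that order, were higher and 0 lower.

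The combination was compared with MAPKi to see what entinostat added. Genes of the HDACi response were again among the largest rises. NMNAT2 went from 5.61 ± 0.20 with MAPKi to 8.76 ± 0.26 with the combination (SD, n = 3), 8.87-fold higher (adjusted p = 3.8e-10, quantile 3.59). VAT1L (3.15 ± 0.12, quantile 3.57), the long non-coding RNAs LINC00052 (2.83 ± 0.14, quantile 3.38) and LINC00624 (2.79 ± 0.13, quantile 3.37), CD24 (2.67 ± 0.12, quantile 3.01), the hormone gene STC1 (2.32 ± 0.10, quantile 2.73) and the carboxypeptidase gene CPM (2.23 ± 0.11, quantile 2.72) rose. ANGPTL7 went from 10.78 ± 0.17 to 5.41 ± 0.12, 41.3-fold lower (-5.37 ± 0.13, quantile -5.20), close to its vehicle level of 5.28 ± 0.24. ERBB3 (-2.33 ± 0.11, quantile -1.84), the spermidine synthase gene SRM (-2.24 ± 0.11, quantile -1.94), the mitochondrial ribosome gene MRPL16 (-2.28 ± 0.12, quantile -1.95), ARHGAP31 (-2.92 ± 0.11, quantile -2.58) and PI15 (-2.64 ± 0.17, quantile -2.65) fell.

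Mitosis genes were higher with the combination than with MAPKi alone. Of 20, 17 rose and 0 fell (18 rose adjusted over the list alone), with a median of 0.56 (quantile 1.00, 20 higher), camera adjusted p = 3.5e-15 and adjusted p = 0.53 with an estimated correlation. CDK1 (1.31 ± 0.13, quantile 1.80), AURKB (1.28 ± 0.13, quantile 1.75) and CDC20, an activator of the anaphase-promoting complex (1.05 ± 0.11, quantile 1.44), rose most, and MKI67 rose by 0.52 ± 0.10 (quantile 0.87). DNA replication genes did not move with them: 3 rose and 10 fell (median -0.30, quantile 0.07 with 7 higher and 4 lower, so of opposite sign, camera adjusted p = 0.94), with MCM5 at -0.92 ± 0.12 (quantile -0.55). Of 14 neuronal genes 8 rose and 0 fell (median 0.49, quantile 0.87 with 10 higher), camera adjusted p = 1.6e-06 and adjusted p = 0.53 with an estimated correlation, led by SYT4 (2.38 ± 0.22, quantile 2.88) and SYN1 (2.18 ± 0.12, quantile 2.67).

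Dedifferentiated-state genes rose in 5 of 12 and fell in 3 (median 0.14, quantile 0.42 with 7 higher and 1 lower), camera adjusted p = 0.0015 and adjusted p = 0.62 with an estimated correlation. SOX2 (1.59 ± 0.12, quantile 2.09), NGFR (1.48 ± 0.10, quantile 1.92) and EGFR (1.28 ± 0.11, quantile 1.77) rose. MET rose by 2.16 ± 0.10 (quantile 2.67), while 3 of 10 receptor tyrosine kinases rose and 2 fell (camera adjusted p = 0.1). Keratinocyte and epithelial markers rose in 3 of 9 and fell in 2, with KRT18 at 1.14 ± 0.12 (quantile 1.55), camera adjusted p = 0.046 and adjusted p = 0.62 with an estimated correlation. All 6 non-homologous end joining genes fell on both scales (median -0.97, quantile -0.59), camera adjusted p = 0.0057 and adjusted p = 0.53 with an estimated correlation, including TP53BP1 (-1.60 ± 0.13, quantile -1.39), XRCC6 (-1.17 ± 0.11, quantile -0.71) and XRCC5 (-0.76 ± 0.10, quantile -0.41). Homologous recombination genes went both ways, with 1 of 17 higher and 10 lower (11 adjusted over the list alone, median -0.39, quantile -0.01 with 5 higher and 3 lower, camera adjusted p = 0.69). MGMT fell by 0.84 ± 0.11 (quantile -0.75), and PARP1 fell by 0.58 ± 0.10 without passing after quantile normalization (quantile -0.10).

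Pathway output genes went both ways between the combination and MAPKi. DUSP6 (0.07 ± 0.17, adjusted p = 0.77), SPRY4 (-0.03 ± 0.12, adjusted p = 0.88) and ETV5 (0.04 ± 0.14, adjusted p = 0.84) did not pass on either scale. CCND1 (0.11 ± 0.11, adjusted p = 0.44), MYC (0.19 ± 0.13, adjusted p = 0.24) and BCL2L11 (0.08 ± 0.11, adjusted p = 0.57) passed after quantile normalization but not on the deposited scale, at 0.61, 0.54 and 0.55. Of the 16 MAPK pathway output genes 5 rose and 3 fell (median 0.09, quantile 0.46), camera adjusted p = 0.0082 and adjusted p = 0.62 with an estimated correlation. MITF fell by 1.09 ± 0.13 (quantile -0.95) and MLANA by 0.47 ± 0.11 (quantile -0.43, and without passing at -0.22, adjusted p = 0.14, once each array's median was subtracted), whereas PMEL rose by 0.35 ± 0.14 (quantile 0.65), a call lost with only the arrays compared (limma adjusted p = 0.059). In total 7200 genes changed, 1267 higher and 5933 lower around a median of -0.23, against 2898 higher and 3430 lower after quantile normalization, with 1265 higher and 3419 lower on both.

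**Figure D3:**
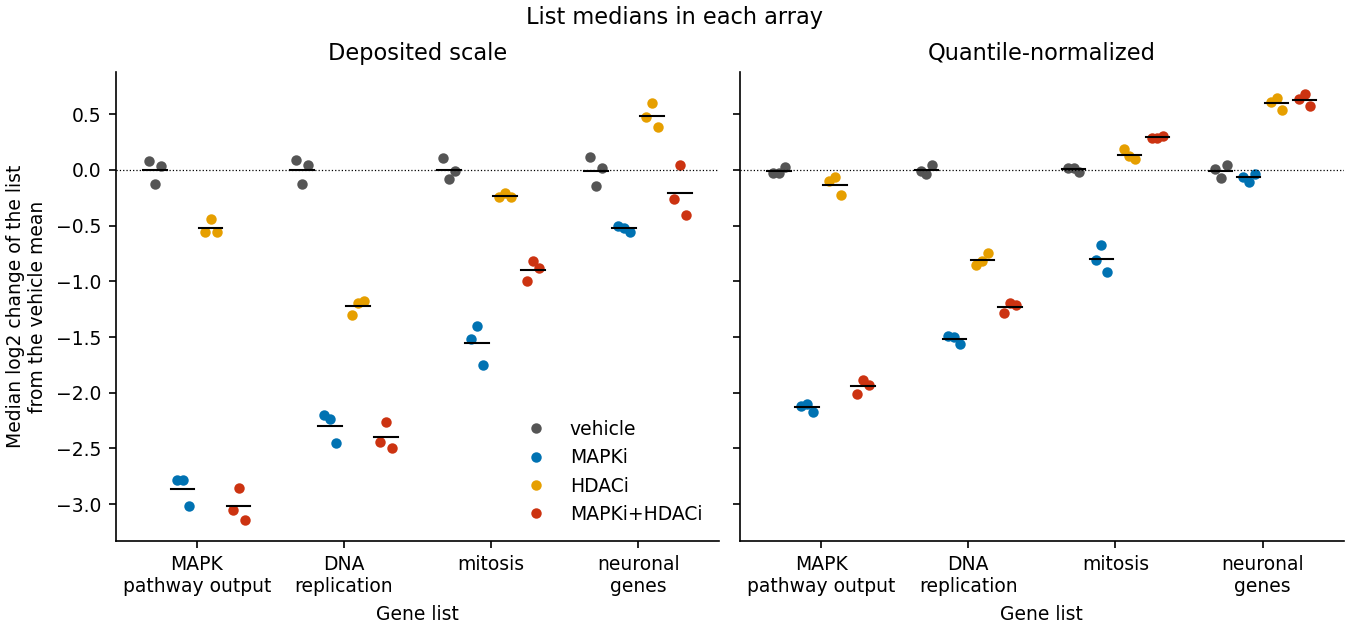
Median log2 change from the vehicle mean (y axis) of 4 gene lists (x axis) in each of 12 arrays, coloured by treatment, on the deposited scale (left) and after quantile normalization (right), with bars at the mean of 3 arrays. Mitosis genes stand higher with the combination than with MAPKi on both scales, while against vehicle they are lower on the deposited scale and higher after quantile normalization.

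The combination was compared with HDACi to see what the MAPK inhibitors added. Pathway output genes fell in all 16 cases (median -2.74, quantile -1.94 with 15 lower), camera adjusted p = 4.7e-12 and adjusted p = 0.26 with an estimated correlation (0.0015 after quantile normalization). SPRY4 was 27.4-fold lower (-4.78 ± 0.12, adjusted p = 5.1e-13, quantile -4.29), NPPC 17.7-fold lower (-4.15 ± 0.11, quantile -3.25), ETV5 16.9-fold lower (-4.08 ± 0.14, quantile -3.63) and DUSP6 14.5-fold lower (-3.86 ± 0.17, quantile -3.42). CCND1 fell by 2.38 ± 0.11 (quantile -1.49) and MYC by 1.35 ± 0.13 (quantile -0.64). TREM1, raised by entinostat alone, fell from 8.71 ± 0.04 to 4.71 ± 0.38 (SD, n = 3), 15.9-fold lower (quantile -3.54). ANKRD1, a target of YAP signalling, fell by 3.51 ± 0.18 (quantile -3.20). In the inflammatory list, 5 of 7 genes fell (median -0.94, quantile -0.13 with 3 lower and 1 higher, camera adjusted p = 0.11), including CXCL8 (-2.62 ± 0.16, quantile -2.37) and MMP1 (-1.81 ± 0.11, quantile -1.44).

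DNA replication genes fell in 19 of 20 (median -1.20, quantile -0.42 with 13 lower and 1 higher), camera adjusted p = 3.3e-06 and adjusted p = 0.43 with an estimated correlation (0.048 after quantile normalization). Homologous recombination fell in 17 of 17 (median -1.02, quantile -0.33 with 9 lower), camera adjusted p = 0.00011 and adjusted p = 0.43 with an estimated correlation (0.039 after quantile normalization), and ribosome biogenesis fell in 10 of 10 (median -1.23, quantile -0.52 with 9 lower), camera adjusted p = 0.00011 and adjusted p = 0.43 with an estimated correlation (0.012 after quantile normalization). Sterol synthesis fell in 12 of 12 (median -1.11, quantile -0.38 with 8 lower and 1 higher), camera adjusted p = 0.00024 and adjusted p = 0.43 with an estimated correlation. GPNMB rose 5.24-fold (2.39 ± 0.14, quantile 3.23), followed by LCTL (1.50 ± 0.09, quantile 2.35), FYB1 (1.37 ± 0.15, quantile 2.15), the growth factor-binding gene IGFBP5 (1.17 ± 0.11, quantile 1.95), the matrix gene MGP (1.10 ± 0.10, quantile 1.89) and the fatty acid-activating gene ACSL1 (0.96 ± 0.11, quantile 1.76).

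Several fixed genes fell against HDACi on the deposited scale but did not pass after quantile normalization: XRCC5 (-0.89 ± 0.10, quantile -0.12), XRCC6 (-1.05 ± 0.11, quantile -0.15), PARP1 (-1.04 ± 0.10, quantile -0.14), MGMT (-0.53 ± 0.11, quantile -0.10), MKI67 (-0.85 ± 0.10, quantile -0.10) and MITF (-0.67 ± 0.13, quantile -0.19). PMEL fell on both (-1.33 ± 0.14, quantile -0.67). MLANA (-0.15 ± 0.11, adjusted p = 0.23, quantile 0.08) and BCL2L11 (0.02 ± 0.11, adjusted p = 0.88, quantile 0.90, which passed) did not. In total 10696 genes changed, 94 higher and 10602 lower around a median of -0.535, against 1664 higher and 1700 lower after quantile normalization. On both scales 88 were higher and 1700 lower, and 926 that fell on the deposited scale were called higher after quantile normalization.

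The interaction tested whether the entinostat effect differed in the presence of MAPKi from that without it, which is also the departure of the combined change from the sum of the separate log2 changes. For 1168 genes it did, 462 above the sum and 706 below, around a median of -0.05. After quantile normalization it did for 907 above and 914 below, with 438 above and 624 below on both. Among MAPK-lowered genes, FST departed by 2.59 ± 0.19 (adjusted p = 1.2e-06), as it was low with MAPKi (6.10 ± 0.25), HDACi (6.76 ± 0.09) and both (5.96 ± 0.20) against 9.48 ± 0.14 in vehicle (SD, n = 3). SPRY4 departed by 1.30 ± 0.17 (adjusted p = 0.00019, quantile 1.16). ANGPTL7 departed by -5.03 ± 0.18 (adjusted p = 1.4e-10, quantile -4.93), TREM1 by -3.43 ± 0.22 (quantile -3.33) and CXCL8 by -2.40 ± 0.23 (quantile -2.22). BCL2L11 departed by -0.91 ± 0.16 (adjusted p = 0.0019, quantile -0.75), at 8.22 ± 0.01 with MAPKi, 8.29 ± 0.15 with HDACi and 8.31 ± 0.15 with both.

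Mitosis genes lay above the sum in 19 of 20 (20 adjusted over the list alone), with a median of 0.84 (quantile 0.90), camera adjusted p = 2.5e-24 and adjusted p = 0.23 with an estimated correlation (0.043 after quantile normalization). DNA replication lay above it in 12 of 20 (16 adjusted over the list alone), with a median of 0.76 (quantile 0.73), camera adjusted p = 1.2e-18 and adjusted p = 0.23 with an estimated correlation (0.019 after quantile normalization). MAPK pathway output lay above it in 6 of 16 and below in 0 (9 and 2 adjusted over the list alone), with a median of 0.59 (quantile 0.40), camera adjusted p = 1.3e-07 and adjusted p = 0.29 with an estimated correlation. Of the fixed genes, MKI67 departed by 0.74 ± 0.14 (adjusted p = 0.003, quantile 0.76), MITF by -0.79 ± 0.18 (adjusted p = 0.01, quantile -0.80) and PMEL by -0.72 ± 0.20 (adjusted p = 0.03, quantile -0.57). DUSP6 (0.67 ± 0.24, adjusted p = 0.12), ETV5 (0.66 ± 0.20, adjusted p = 0.063), MYC (0.28 ± 0.18, adjusted p = 0.42) and MLANA (-0.11 ± 0.15, adjusted p = 0.77) did not pass, although DUSP6 (0.71, adjusted p = 0.048) and ETV5 (0.70, adjusted p = 0.032) did with each array's median subtracted. CCND1 passed after quantile normalization but not on the deposited scale (0.31 ± 0.15, adjusted p = 0.27, quantile 0.44). The repair genes XRCC5 (0.05 ± 0.15, adjusted p = 0.89, quantile 0.16), XRCC6 (-0.02 ± 0.16, adjusted p = 0.96, quantile 0.06, so of opposite sign), PARP1 (0.06 ± 0.14, adjusted p = 0.86, quantile 0.19) and MGMT (-0.14 ± 0.15, adjusted p = 0.68, quantile -0.21) did not pass on either scale.

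The genes changed by each treatment alone overlapped. Both treatments lowered 4871 genes, where 3589 would coincide if calls were independent, and both raised 155 against 44.98. Opposite calls were rarer than that on the deposited scale: 70 genes were raised by MAPKi and lowered by HDACi (161.2 under independence), and 810 were lowered by MAPKi and raised by HDACi (1001 under independence). After quantile normalization, 825 were higher in both (407.2 under independence), 889 lower in both (428.1) and 384 higher with MAPKi and lower with HDACi (465.5). Lower with MAPKi and higher with HDACi were 476, more than the 374.5 under independence. Independence takes no account of the downward shift of bright genes with both treatments, which would raise the number lower in both on the deposited scale. Both comparisons used the same 3 vehicle arrays, which alone would make their changes covary. The covariance across genes was 0.105, against a median of 0.0091 in 20 simulations of unchanged groups set against shared vehicle arrays. In these 0 genes were called in both, which was near certain since none was changed. That count does not show how much of the overlap comes from the shared arrays. After quantile normalization the covariance was 0.0431. The correlation across genes was 0.386 (0.211 after quantile normalization), below the 0.5 of those simulations, in which shared vehicle arrays were the only source of covariance, and genes are not independent replicates.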

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

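The entinostat effect differed with and without MAPKi for 1168 genes, which is a difference between groups. Tests marked as chosen afterwards below were picked only once the result had been seen. The entinostat change with MAPKi minus that without, on the log2 scale, was positive for FST 2.59 (limma adjusted p = 1.2e-06), ELOVL2 2.25, EDN1 2.13, WNK4 2.00, REM1 1.98, EFR3B 1.97, TFAP2C 1.79, CEMIP 1.74, UNC5CL 1.70, TMEM158 1.69, SPRY4 1.30 and MKI67 0.74. It was negative for ANGPTL7 -5.03 (limma adjusted p = 1.4e-10), TREM1 -3.43, PI15 -2.81, ANKRD1 -2.57, TMEM47 -2.52, CXCL8 -2.40, ALCAM -2.22, MMP13 -2.13, MATN2 -1.98, JPH1 -1.94, BCL2L11 -0.91, MITF -0.79 and PMEL -0.72. The sign does not give the size of either change, since FST fell with HDACi alone (9.48 to 6.76) and stood at 6.10 with MAPKi and 5.96 with both, whereas ANGPTL7 fell more in the presence of MAPKi (10.78 to 5.41) than without it (5.28 to 4.94).

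By list, the median difference was 0.59 for MAPK pathway output, 0.33 for homologous recombination (6 of 17 genes above the sum, 8 adjusted over the list alone), 0.09 for base excision repair, 0.76 for DNA replication, 0.84 for mitosis, 0.54 for the dedifferentiated and invasive melanoma state (7 of 12 above and 2 below), 0.30 for receptor tyrosine kinases (4 of 10 above) and -0.17 for inflammatory secretion (3 of 7 below). Their camera adjusted p, in that order, were 1.3e-07, 6.6e-05, 0.028, 1.2e-18, 2.5e-24, 0.0013, 0.00088 and 0.021. With an estimated correlation the adjusted p were 0.29, 0.58, 0.66, 0.23, 0.23, 0.58, 0.56 and 0.58, so none passed. Signal was also present in probe sets with no gene name here, of which 70 with MAPKi, 280 with HDACi and 134 with the combination were at least 2-fold higher than vehicle on both scales.

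Regrouping the arrays of each comparison of 2 groups gave 10 splits into 3 and 3, which cannot give a share under 0.05. In each of the 5 comparisons the real split alone, 1 of 10, reached its count, and the highest other split had 0 changed genes. Every other split put arrays of both groups on each side, so the treatment difference entered the spread within sides. Their count of 0 was therefore built in and gives no rate of false calls. The real counts were 10094 for MAPKi, 6937 for HDACi and 11479 for the combination against vehicle, 7200 for the combination against MAPKi and 10696 against HDACi. For the interaction, 1 of 100 reassignments of the residuals of an additive fit, the real one, reached 1168, and the highest other had 1. That rank argues against chance assignment of arrays for the count as a whole. The residuals still held the real departures, however, and other reassignments moved these into the spread within groups. Their low counts were thus partly built in and give no rate of false calls.

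Most genes were lower on the deposited scale after treatment. The test of 1 factor per array was chosen only after the result was seen, and the test of a stray array before. A single factor applied to each finished array would shift bright and dim genes alike, yet the brightest bin minus the dimmest was -1.152 for the combination against vehicle. For the same comparison a stray array is argued against as well, since at least 94.1% of the changed genes were lower whichever array was left out. Less RNA per cell, or scaling before deposition combined with background at the dim end, could each give this pattern, and no biological explanation was tested.

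Mitosis genes were higher after the combination than after MAPKi, in 17 of 20 genes. The test of an intensity-dependent shift was chosen before the data were examined, and the tests of scaling, of a general return to proliferation and of more cells in G2 or mitosis only after the result was seen. The list's median lay at percentile 100 of 10000 lists matched on mean level, which argues against an intensity-dependent shift. After quantile normalization the scaling test gave a median of 1.00, against an SD between arrays of at most 0.121. That test cannot decide on scaling. The median over all genes was -0.23 on the deposited scale, so quantile normalization could hardly lower a list that had risen. What it shows is that the list was higher on both scales. A general return to proliferation stays open: mitosis minus DNA replication was 0.764 higher with the combination than with MAPKi (lowest combination array 1.448, highest MAPKi array 0.84, smallest exact 2-sided p for 3 against 3 of 0.1), but HDACi without MAPKi raised it over vehicle by 0.995, and both lists lay above the sum by similar medians (0.84 and 0.76). Whether more cells were in G2 or mitosis stays open, because its test (85% of mitosis genes and 3 of 20 replication genes higher on both scales) restates the observation that prompted it and lends no support, and cell cycle phase was not measured.

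The combined change differed from the sum of the separate changes for 1168 genes. The tests of the array's floor and of entinostat-raised genes were chosen before the data were examined, and the test of scaling only after the result was seen. A hard floor at log2 2.67 explains few genes above the sum, as 0.649% (3 of 462) had a predicted level below it. The weak response of dim genes reaches above that level, however. The median combination change against vehicle was -0.31 in the bin at a mean log2 of 4.1, against -1.32 at 7.99. Whether background above the floor plays a part is therefore not decided by this test. After quantile normalization 90.9% of departures kept their call, so most did not depend on the choice between these scales. That test cannot decide on scaling. The median departure over all genes was only -0.05 on the deposited scale, so there was little general shift to remove. The number of departing genes did depend on the scale, at 1821 after quantile normalization. Of the 462, 343 were lowered by both treatments alone, so that shared targets which can fall only once could account for part of them, a hypothesis without a test. That entinostat-raised genes respond less under MAPKi stays open: among 588 genes picked on replicate 1, 60.2% had a smaller effect after quantile normalization and 79.4% on the deposited scale, with quantile medians of 1.13 with and 1.20 without MAPKi. The 60.2% met the bound set beforehand, but an exact 95% interval of 56.1 to 64.2, added only after the result was seen and taking genes as independent, reaches below that bound and moved the verdict to open. The choice of genes also limits this test. Picking on the entinostat effect without MAPKi favours genes in which that effect is the larger. Most of them could thus show a smaller effect with MAPKi even if departures went equally both ways.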

How the results depend on the processing

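How arrays are scaled decided most counts, and the cause was not tested. After quantile normalization the changed genes were 4233 for MAPKi, 6755 for the combination, 3364 for the combination against HDACi and 1821 for the interaction. Higher were 2205 (MAPKi), 2696 (HDACi), 3225 (combination), 2898 (combination against MAPKi), 1664 (against HDACi) and 907 (interaction). Lower were 2028 (MAPKi), 3082 (HDACi), 3530 (combination), 3430 (combination against MAPKi) and 1700 (against HDACi), and 1714 genes moved the same way with MAPKi and HDACi. With each array's median subtracted, 6473 (combination against HDACi) and 1769 (interaction) changed. Higher were then 3876 (MAPKi), 3027 (HDACi), 5519 (combination), 2981 (combination against MAPKi), 3262 (against HDACi) and 854 (interaction), lower were 3296 (MAPKi), 4813 (combination), 3873 (combination against MAPKi) and 3211 (against HDACi), and 3273 moved the same way with MAPKi and HDACi. Without the dimmest 40% of genes, where fewer genes are tested, higher were 259 (MAPKi), 339 (combination) and 50 (combination against HDACi).

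Of list medians, 60 of 192 changed sign after quantile normalization. Where camera passed on either scale, its direction against other genes reversed in 8 cases, with quantile medians of 0.32 (MAPKi) and 0.392 (combination) for antigen presentation, and for lysosome (0.268 MAPKi, 0.276 combination, 0.37 combination against HDACi), mitosis (0.288 combination) and amino acid and stress response (0.591 combination, 0.315 combination against HDACi). Direction reversed for the genes MGMT with MAPKi (0.114), MYC with HDACi (0.276), and PMEL (0.542) and MKI67 (0.008) with the combination. Of these, MGMT (limma adjusted p = 0.316) and MKI67 (limma adjusted p = 0.937) did not pass after quantile normalization, so only their sign changed. With each array's median subtracted it reversed for MGMT (0.161 MAPKi, 0.067 combination against HDACi, passing in neither), MLANA (0.508 MAPKi, 0.293 combination, 0.449 combination against HDACi) and PMEL (0.545 combination). MLANA was dim, with group means of 3.76 to 4.27 on the log2 scale, and dim genes moved little while array medians fell. Subtracting a lower median raises such a gene whatever its own change. The cause was not tested.

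With the replicate number as a block (replicate block), 10217 (MAPKi), 7004 (HDACi), 11554 (combination), 7241 (combination against MAPKi), 10811 (against HDACi) and 1159 genes (interaction) changed. Leaving out each array in turn gave 8862 to 10328, 6091 to 7178, 10751 to 11770, 6342 to 7672, 9551 to 11391 and 859 to 1294 in the same order, and all 240 counts stayed within the range called the same. So did all 20 counts with trend and robust variance, with the mean of a gene's probe sets and with all probe sets. Among list results after quantile normalization, 166 kept their camera call (passing in the same direction, or passing on neither scale), 11 lost significance, 7 gained it and 8 reversed. For the genes named, these numbers were 207, 13, 7 and 4, and 211, 5, 9 and 6 with each array's median subtracted. Without the dimmest 40% of genes, 20 list results lost significance, 8 gained it and 164 kept their call. With 1 array left out, 16 list results lost it, 12 gained it and 2276 kept their call, and for lists with each array's median subtracted these were 1, 9 and 182. For the genes named, 17 lost it, 6 gained it and 2749 kept their call with 1 array left out. The block cost 1 list result its significance, gave it to 2 and left 189 as they were, and for the genes named these were 1, 1 and 229. PMEL in the combination against MAPKi lost significance with only the arrays compared, with the block and with all probe sets. With each array's median subtracted, significance was lost for MITF (combination, and combination against HDACi), MLANA (HDACi, and combination against MAPKi) and PMEL (MAPKi). Scaling on ERCC rows was not run because none could be identified. Signal over background limits what can be seen at the dim end, where a gene close to background has little room to fall, and 3 arrays per group of uncertain replicate type limit every p-value.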

Other observations

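Among the 14809 probe sets with no gene name here, 415 were higher and 6608 lower with MAPKi, 1156 higher and 3186 lower with HDACi, and 693 higher and 8520 lower with the combination, against vehicle on the deposited scale (limma, adjusted p under 0.05).

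The 706 genes below the sum of the separate changes included 237 that rose with MAPKi alone, 320 that rose with HDACi alone and 54 that fell with both. TMEM47 stood at a log2 intensity of 6.41 in vehicle, 8.69 with MAPKi, 8.69 with HDACi and 8.45 with both (means of 3 arrays). ALCAM stood at 5.75, 8.20, 7.86 and 8.10 in the same order. ELOVL2, above the sum, stood at 9.06, 5.51, 8.62 and 7.32, and the transcription factor gene TFAP2C at 10.84, 7.22, 10.49 and 8.67, so both means were near the vehicle level with HDACi and higher with the combination than with MAPKi. EDN1, which encodes endothelin-1, stood at 7.45, 4.22, 5.93 and 4.83.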
